A study of Arabidopsis thaliana with 12 samples.

How the data were processed

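Poly(A) RNA from seedlings of Arabidopsis thaliana, accession Col-0, at 10 days of age was sequenced in 12 libraries. The libraries formed 4 groups of 3: wild type in control, wild type after 2.5 h of heat, the mutant atdamt1 in control, and atdamt1 after 2.5 h of heat. The groups and replicate numbers were taken from the labels. These give 0 h for every control and 2.5 h for every heat library. They name no control kept for 2.5 h without heat, so a change over that time cannot be told apart from heat. The labels do not say that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be partly technical.

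The deposited table gives RPKM values (reads per kilobase of gene model, scaled to the reads of the library), made by the authors, for 32833 genes in 12 columns. STAR, DESeq2 and the genome build TAIR10 are named in the submitters' processing notes without a role or a version. The library kit keeps strand, per the labels' protocols; the counting tool, its strand setting and the annotation release are not given in the sources used here. Genes overlapping or antisense to another gene are therefore uncertain. A fold change between RPKM values is relative to the library total, and it carries no information on the absolute amount of RNA.

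RPKM values were multiplied by the exon-union length in the TAIR10.1 annotation, which held 32548 of the genes. Of the 24599 such genes above 0, 24448 (99.4%) gave whole reads in all 12 libraries within a tolerance of 0.1 reads. The step between values gave depths of 21720000 to 23519000 reads per library, and 18542000 to 21538000 reads per library were recovered in genes with a length. Chloroplast-encoded and mitochondrial-encoded genes had no length and entered as RPKM values. Floors for a group at 0 were set at 3 reads per library and cover counting error only. Replicates were compared before averaging: the chi-square per degree of freedom between libraries of a group was 12.4 to 43.7, and no pair was counted as 1 sample.

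Genes with an RPKM of at least 1 in at least 3 libraries were tested, 17628 in all. Values were taken as log2(RPKM + 1), so a fold change understates the change of genes with low values. Limma 3.58.1 in R 4.3.3 fitted all 12 libraries together with 1 mean per group, 8 residual degrees of freedom, and a mean-variance trend, two-sided. Adjusted p-values are Benjamini-Hochberg values from limma over the genes tested, with a threshold of 0.05. The 5 contrasts were heat in each genotype, genotype in each treatment, and the difference between the heat responses. Tables were prepared with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

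The design, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The lists held 387 entries in 21 lists. Entries were matched by locus and dropped where the reference pairs the locus only with other names, which removed 5 (HSP14.2, HSP70-4, MTB, EXPRS and SAND). The 8 ONSEN retrotransposon loci were not analysed here. The 18 lists with at least 3 tested members were tested with camera (limma) at a preset correlation of 0.01, with adjustment over all 90 tests, and again with an estimated correlation. The estimated correlation gave no call for any fixed list, not even for small heat shock proteins after heat. Its p-values therefore do not argue against a change of a list. Camera compares the members of a list with the other genes tested, so an upward or downward call is relative to those genes. Medians and means of a list are counted from 0, so a list below 0 can be up in camera where most genes fell. The named genes were AT1G19340; up to 6 rises and 6 falls per contrast with a mean RPKM of at least 5 in the higher group and no overlap between groups (up to 5 and 5 for the interaction); and up to 3 members of each list past the threshold, or the member with the smallest p. Members that moved against their list may also be named, and genes named outside this rule are said to be chosen after their values were seen.

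The fit was tested on simulated reads for 16910 genes, with 200 genes changed in the wild-type heat libraries. For heat in wild type, 37.3% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold were recovered. For the genotype difference in heat the shares were 34.3%, 83.6% and 100%, and for the interaction 7.46%, 59.7% and 95.5%. Of the calls, 8 of 154, 10 of 155 and 8 of 116 were genes that had not been changed. Noise in this simulation was drawn separately for each gene and library, and few genes were changed. The real heat contrasts called 10926 and 11730 of 17628 genes, and the real libraries share structure. The recovered shares therefore do not carry over to the real contrasts.

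Alternatives were another pseudocount, filters, median-of-ratios, TMM and quantile scaling, fits of single contrasts, a replicate block, variance settings, array weights, stricter thresholds and leaving out each library. Voom weights on the recovered reads, the chloroplast-encoded share as a covariate, the average of the genotype contrasts and lists without wild-type heat replicate 1 or with that covariate were added after seeing the data.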

Results

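Gene expression was measured in seedlings at 10 days of age in 12 libraries, 3 for each combination of genotype (wild type or atdamt1) and treatment (control, labelled 0 h, or 2.5 h of heat). The series title concerns METTL4, a putative adenine methyltransferase, and thermotolerance, and the design compares control and heat-treated seedlings of both genotypes. Depth was 21720000 to 23519000 reads per library. The first principal component held 79.4% of the variance and separated the heat libraries from the control libraries.

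AT1G19340, the METTL4 homolog, annotated as a methyltransferase-like protein, was lower in every atdamt1 library than in every wild-type library of the same treatment. Its locus on chromosome 1, positions 6684467 to 6687116 of TAIR10.1 on the plus strand, has 8 exon blocks. Wild type held 2.87 ± 0.32 RPKM in control and 1.39 ± 0.13 RPKM after heat (SD, n = 3). The atdamt1 control libraries held 0.808, 0.913 and 1.29 RPKM and the atdamt1 heat libraries 0.342 ± 0.17 RPKM, ratios of the means to wild type of 0.349 and 0.246. On the log2 scale the differences were -0.96 ± 0.14 (SE, adjusted p = 0.114, limma) in control and -0.84 ± 0.14 (adjusted p = 0.208, limma) in heat, and neither passed the threshold. Array weights gave adjusted p = 0.0355 and 0.0428 in these contrasts, and a pseudocount of 5 gave 0.0281 in control. AT1G19340 fell with heat in wild type by 0.69 ± 0.14 (adjusted p = 0.00102, limma), and this call was lost under median-of-ratios (adjusted p = 0.0513), TMM (adjusted p = 0.0513) and quantile scaling (adjusted p = 0.354). In atdamt1 it fell by 0.58 ± 0.14 (adjusted p = 0.00312, limma), which was lost under quantile scaling (-0.32, adjusted p = 0.101) and with the chloroplast-encoded share of each library as a covariate (-0.45, adjusted p = 0.145), a setting chosen after seeing the data. With 1 added to values this low, these log2 falls understate the change. The ratio of the means to wild type was lower after heat (0.246) than in control (0.349), so the relative fall of the means was larger in atdamt1. The interaction was not called.

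**Figure D1:**
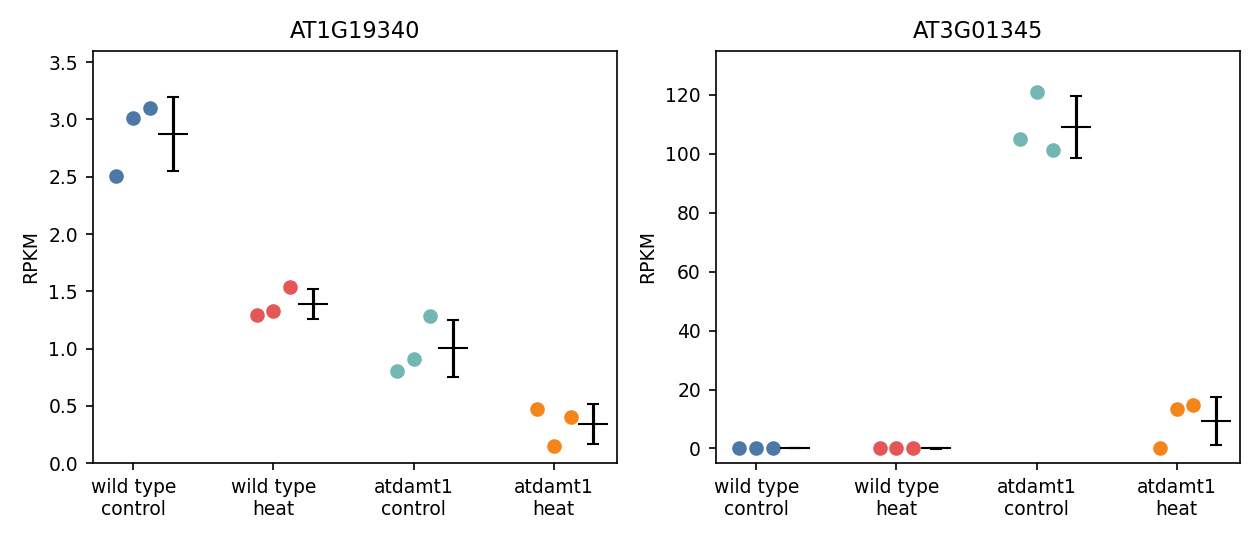
RPKM of AT1G19340 (left) and AT3G01345 (right) in each library, with 3 libraries per group as points and the mean ± SD in black. AT1G19340 lies at 0.342 RPKM on average in atdamt1 after heat and at 2.87 in wild type in control. AT3G01345 lies on average at 109 RPKM in atdamt1 in control and at 0.16 in wild type in control.

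The largest named rises with heat in wild type were of small heat shock proteins, and the largest named falls included trans-acting siRNA precursors. The class I small heat shock protein HSP17.6C-CI rose from 0.101 ± 0.134 to 1894 ± 835 RPKM (SD, n = 3), a log2 change of 10.67 ± 0.35 (SE). HSP17.7-CII, HSP17.6-CII, HSP17.6A-CI, HSP17.8-CI and the mitochondrial HSP23.6-M rose by 10.23, 9.82, 9.52, 9.51 and 8.79. The germin-like gene GER3 fell from 1761 ± 151 to 49.5 ± 4.92 RPKM (log2 -5.12 ± 0.16), and the trans-acting siRNA precursors TAS1C and TAS1B fell as well (-3.93 and -3.83). TAS1A fell from 25.2 to 0.329 RPKM. The hevein-like gene HEL (-3.78) and the GDSL-lipase-like gene GLL23 (-3.68) were also among the largest falls.

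In all, 10926 of 17628 genes passed adjusted p below 0.05 in limma with Benjamini-Hochberg adjustment, 1659 higher and 9267 lower, and 622 and 2967 of them changed at least 2-fold. The median gene moved by -0.41 (log2) in wild type and -0.44 in atdamt1 on the deposited scale, so a fall of that size is level with the median gene. Genes counted in all 4 scalings kept their direction and call when this shift was removed. Under median-of-ratios scaling, 5062 were higher and 4715 lower; under TMM, 5106 and 4657; under quantile normalization, 4001 and 4670. Directions held in all 4 scalings for 1627 higher and 3842 lower genes, and 71 genes called lower as deposited were called higher under median-of-ratios. The 4 scalings include the deposited one, where a rise had to overcome the median shift. Counts held in all 4 scalings, here and for the lists, therefore favour falls over rises.

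Of 17 small heat shock proteins, 16 rose in wild type, in all 4 scalings and also adjusted over the list alone, and HSP15.4 did not pass (HSP15.4 -0.10 ± 0.23, adjusted p = 0.736, limma). The list was up in camera (adjusted p = 2.34e-29, and adjusted p = 0.366 with an estimated correlation). Of 29 other chaperones and co-chaperones outside the ER, 19 rose, 1 fell and 9 did not pass, with the same counts adjusted over the list alone; 18 rises and no fall held in all 4 scalings. The disaggregase HSP101 rose by 7.25 ± 0.35, HSP90.1 by 7.49 ± 0.35 and the co-chaperone HOP3 by 7.17 ± 0.29 (camera adjusted p = 6.31e-18, and adjusted p = 0.421 with an estimated correlation). Heat libraries differed in this response: the mean log2 level of the small heat shock proteins was 9.66 in wild-type replicate 1 against 8.60 and 8.82 in the other wild-type libraries.

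Among 16 heat shock transcription factors, 6 rose and 4 fell, with the same counts adjusted over the list alone, and 2 of the falls held in all 4 scalings. Under quantile normalization 11 were higher and 2 lower. HSFA2 rose by 8.63 ± 0.41, HSFA7A by 4.88 ± 0.23 and HSFB2A by 4.26 ± 0.23 (camera adjusted p = 0.000166, and adjusted p = 0.421 with an estimated correlation). Of 11 other heat-response regulators, 4 rose and 3 fell, as when adjusted over the list alone, and no fall held in all scalings, with 5 higher and 0 lower under median-of-ratios scaling. The coactivator MBF1C rose by 6.98 ± 0.22, the transcription factor DREB2A by 6.18 ± 0.28 and the light and temperature regulator PIF4 by 0.95 ± 0.23 (camera adjusted p = 0.00312, and adjusted p = 0.421 with an estimated correlation).

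Endoplasmic reticulum folding genes went the other way: 14 of 15 fell and 1 rose, with the same counts adjusted over the list alone, and 9 falls held in all 4 scalings. The calreticulin CRT1 fell from 153 to 13.0 RPKM (log2 -3.46 ± 0.13). The disulfide isomerase PDIL2-1 (-2.38) and the ER HSP90 protein SHD (-1.57) fell too, in all 4 scalings. The J-domain co-chaperone ERDJ3A was the riser, by 4.26 ± 0.36 (camera adjusted p = 0.00832 for the list, and adjusted p = 0.640 with an estimated correlation).

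Of 34 nuclear-encoded photosynthesis genes, 27 rose and 4 fell, also adjusted over the list alone; 17 rises and 1 fall held in all 4 scalings. The light-harvesting genes LHCB2.1 and LHCB2.2 each rose by 3.04, and LHCB1.1 rose by 2.29 (camera adjusted p = 3.56e-17, and adjusted p = 0.421 with an estimated correlation). Of 19 reactive oxygen genes, 8 rose and 5 fell, as when adjusted over the list alone, with 7 and 2 in all 4 scalings and 12 higher and 2 lower under median-of-ratios scaling. The zinc-finger regulators ZAT10 and ZAT12 rose by 4.78 and 4.59, while the superoxide dismutase CSD2 fell (-2.46) (camera adjusted p = 0.000415, and adjusted p = 0.421 with an estimated correlation).

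Hormone lists were mixed. For abscisic acid and dehydration, 5 of 24 rose and 6 fell, or 4 and 6 adjusted over the list alone. Camera gave an upward call (adjusted p = 0.00498, and adjusted p = 0.787 with an estimated correlation), relative to the other genes. The list had a median of 0.047 and a mean of -0.010, while the median over all genes was -0.41. In this list 5 rises and 3 falls held in all 4 scalings, and under median-of-ratios scaling the balance turned to 11 higher and 4 lower. The galactinol synthase GOLS1 rose by 4.01, the NAC factor RD26 by 1.44, and the dehydration gene RD29A fell (-1.80). For salicylic acid, 6 of 16 rose and 4 fell, also adjusted over the list alone, with 6 and 2 in all 4 scalings and 10 higher and 2 lower under median-of-ratios scaling. The transcription factors WRKY70 and WRKY33 rose by 2.81 and 2.69 and the receptor kinase FRK1 fell (-1.45) (camera adjusted p = 0.00076, and adjusted p = 0.421 with an estimated correlation). For jasmonic acid, 2 of 13 rose and 6 fell, also adjusted over the list alone. The repressor JAZ9 rose by 1.29, no fall held in all 4 scalings, and under median-of-ratios scaling 3 were higher and 1 lower. Camera had an upward sign (adjusted p = 0.445) against a median of -0.57 and a mean of -0.22. For auxin, 9 of 27 rose and 5 fell, also adjusted over the list alone, with 9 and 4 in all 4 scalings and 14 higher and 4 lower under median-of-ratios scaling. The cell-wall enzyme XTH22 rose by 4.12 and the amido synthetase GH3.5 by 1.64, and the auxin biosynthesis gene YUC8 fell (-1.34) (camera adjusted p = 6.61e-05, and adjusted p = 0.631 with an estimated correlation).

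Of 19 clock genes, 8 rose and 5 fell, as when adjusted over the list alone, with 8 and 3 in all 4 scalings. Under TMM 11 were higher and 4 lower, and 12 and 4 under quantile normalization. RVE1 rose by 2.19, and TOC1 (-1.28) and FKF1 (-2.25) fell (camera adjusted p = 0.00312, and adjusted p = 0.601 with an estimated correlation). With controls labelled 0 h, time of day was not separated from heat for these genes. Of 21 nucleic acid methylation genes 16 fell and none rose, also adjusted over the list alone, and 8 falls held in all 4 scalings, with 3 higher and 8 lower under median-of-ratios scaling (camera adjusted p = 0.127). ALKBH1A, an AlkB-family dioxygenase gene (-1.79), ECT4, a reader of methylated RNA (-1.18), and the DNA glycosylase gene DME (-1.15) were among them. Cell cycle genes gave 1 rise and 5 falls of 20, or 1 and 4 adjusted over the list alone, with a median of -0.17, a mean of -0.14 and an upward sign in camera (adjusted p = 0.23), and under median-of-ratios scaling the balance reversed to 6 higher and 1 lower with a median of 0.27. PCNA2, the replication clamp, fell (-1.61) in all 4 scalings.

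Ribosome biogenesis genes gave 6 falls of 8, also adjusted over the list alone, with 2 in all 4 scalings, BRX1-1 (-1.63) and NOP5-1 (-1.34) (camera adjusted p = 0.429). Flowering-time genes gave 3 falls of 8 as deposited and 0 adjusted over the list alone, FLM (-0.26), MAF3 (-0.32) and MAF2 (-0.30), and these turned to 0.20, 0.15 and 0.17 under median-of-ratios scaling, where the list gave 3 higher and 0 lower (camera adjusted p = 0.478, an upward sign against a median of -0.19). MAF3 (adjusted p = 0.0517) and MAF2 (adjusted p = 0.0630) were lost with the chloroplast-encoded share as a covariate. FLM and MAF2 were lost in the fit of the wild-type libraries alone, and MAF2 with no filter, the replicate block or array weights. Of 9 root markers, SCR (-1.88) and PYK10 (-2.61) fell in all 4 scalings, also adjusted over the list alone (camera adjusted p = 0.876). Of 4 flower organ markers 1 was tested, SEP3 (0.62 ± 0.46, adjusted p = 0.254, limma), and of 9 seed storage genes 0 passed the expression filter. Of 11 reference genes for RT-qPCR, 4 rose and 1 fell, also adjusted over the list alone, with UBQ10 up by 0.88 and GAPC1 by 0.47. Of these 11, 10 were higher and 0 lower under median-of-ratios scaling (camera adjusted p = 0.000732, and adjusted p = 0.421 with an estimated correlation).

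In atdamt1, HSP17.6C-CI rose with heat from 0.114 ± 0.1 to 1335 ± 725 RPKM (log2 10.08 ± 0.35), and HSP17.7-CII, HSP17.6A-CI, HSP17.6-CII and HSP17.8-CI rose by 9.78, 9.39, 9.26 and 8.93. HSP23.6-M was at 0 in the atdamt1 control libraries and at 304 RPKM after heat, at least 2400-fold higher against a floor of 3 reads per library. GER3 fell by 4.42 ± 0.16, and the precursors TAS1A (-4.33), TAS1C (-4.11), TAS1B (-3.98) and TAS2 (-3.74) fell too. The unnamed gene AT3G01345 fell by 4.17 ± 0.77 (adjusted p = 0.000549, limma), from 109 ± 10.4 RPKM in control to 0, 13.4 and 14.8 RPKM after heat.

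A total of 11730 genes passed in limma with Benjamini-Hochberg adjustment, 1817 higher and 9913 lower, and 775 and 3052 changed at least 2-fold. Median-of-ratios scaling gave 4840 higher and 4793 lower, TMM 4807 and 4809, and quantile normalization 4051 and 5175; 1803 higher and 4345 lower genes held in all 4 scalings. The chloroplast-encoded share of the RPKM sum was 6.01%, 3.17% and 5.58% in the atdamt1 heat libraries, 0.628%, 4.05% and 0.39% in the wild-type heat libraries and 0.32% to 1.07% in controls. With that share as a covariate, chosen after seeing the data, 6489 genes passed in atdamt1. The share differed along with treatment in atdamt1, so a lost call need not mean a smaller change. NOP5-1 lost its call at -1.47, against -1.48 without the covariate, while JAZ2 shrank from -0.72 to -0.22.

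**Figure D2:**
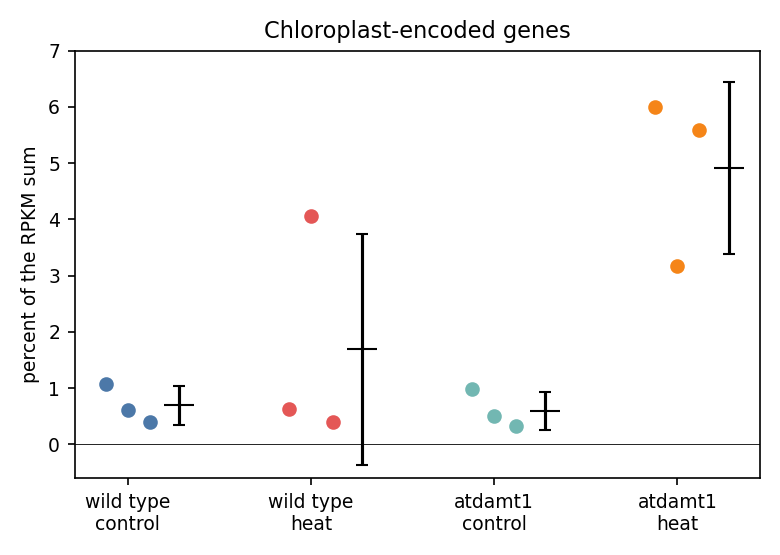
Percent of each library's RPKM sum held by chloroplast-encoded genes, with 3 libraries per group as points and the mean ± SD in black. The atdamt1 heat libraries lie at 3.17% to 6.01% and the wild-type heat libraries at 0.39% to 4.05%.

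In atdamt1, 16 of 17 small heat shock proteins rose in all 4 scalings, also adjusted over the list alone (camera adjusted p = 3.37e-28, and adjusted p = 0.366 with an estimated correlation). Other chaperones gave 16 rises and 3 falls of 29, also adjusted over the list alone, and no fall held in all 4 scalings, with 23 higher and 0 lower under median-of-ratios scaling. HSP90.1 rose by 7.13 and HSP101 by 6.88 (camera adjusted p = 4.72e-14, and adjusted p = 0.539 with an estimated correlation). Heat shock factors gave 7 rises and 5 falls of 16, also adjusted over the list alone, of which 7 and 1 held in all 4 scalings and were the counts under median-of-ratios scaling, with HSFA2 up by 7.81 and HSFA7A by 4.54 (camera adjusted p = 8.03e-05, and adjusted p = 0.421 with an estimated correlation). The other regulators gave 4 rises and 3 falls of 11, also adjusted over the list alone, with no fall in all 4 scalings and 4 higher and 0 lower under median-of-ratios scaling. MBF1C rose by 6.61 and DREB2A by 5.98, and the list had a median of -0.15, a mean above 0 and an upward call in camera (adjusted p = 0.00498, and adjusted p = 0.433 with an estimated correlation). ER folding genes gave 14 falls and 1 rise of 15, also adjusted over the list alone, with 11 falls in all 4 scalings. CRT1 (-3.36) and PDIL2-1 (-2.31) fell, and ERDJ3A rose by 3.74 (camera adjusted p = 0.00792, and adjusted p = 0.640 with an estimated correlation).

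Photosynthesis genes gave 24 rises and 5 falls of 34, also adjusted over the list alone, with 15 and 3 in all 4 scalings. LHCB2.1 and LHCB2.2 rose by 3.74 (camera adjusted p = 3.3e-15, and adjusted p = 0.421 with an estimated correlation). Reactive oxygen genes gave 6 rises and 8 falls of 19, also adjusted over the list alone, with 6 and 4 in all 4 scalings, and under median-of-ratios scaling the balance turned to 11 higher and 4 lower. ZAT12 was up by 4.49 and CSD2 down (-2.87), and the list had a median of -0.071, a mean of 0.15 and an upward call (adjusted p = 0.0192, and adjusted p = 0.601 with an estimated correlation). Abscisic acid genes gave 6 rises and 6 falls of 24, also adjusted over the list alone, with 6 and 2 in all 4 scalings, 12 higher and 3 lower under median-of-ratios scaling, and RD26 up by 1.80 (camera adjusted p = 0.00242, and adjusted p = 0.787 with an estimated correlation). Salicylic acid genes gave 7 rises and 4 falls of 16, also adjusted over the list alone, with 7 and 2 in all 4 scalings, 9 higher and 2 lower under median-of-ratios scaling, and the immune regulator CBP60G up by 1.74 (camera adjusted p = 0.000287, and adjusted p = 0.421 with an estimated correlation). Jasmonic acid genes gave 1 rise and 5 falls of 13, also adjusted over the list alone, and OPR3, JAZ2 and AOC2 lost their calls under median-of-ratios scaling, which gave 2 higher and 1 lower (3 and 1 under TMM). OPR3 and JAZ2 lost theirs also with the chloroplast-encoded share as a covariate. The median was -0.41 and the mean -0.28 under an upward sign in camera (adjusted p = 0.538). Auxin genes gave 10 rises and 3 falls of 27, also adjusted over the list alone, and these held in all 4 scalings, with 18 higher and 3 lower under median-of-ratios scaling. XTH22 was up by 3.54 and the amido synthetase GH3.6 by 2.49 (camera adjusted p = 7.76e-07, and adjusted p = 0.539 with an estimated correlation). Clock genes gave 10 rises and 5 falls of 19, also adjusted over the list alone, and these held in all 4 scalings, with 13 higher and 5 lower under median-of-ratios scaling. RVE1 was up by 2.59, LNK2 up by 1.93 and ELF4 down (-1.86) (camera adjusted p = 0.000287, and adjusted p = 0.539 with an estimated correlation).

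The methylation list gave 13 falls of 21 in atdamt1, also adjusted over the list alone, 8 in all 4 scalings, among them ALKBH1A (-1.76), ECT4 (-1.29) and DME (-1.09), with 4 higher and 8 lower under median-of-ratios scaling (camera adjusted p = 0.216). Cell cycle genes gave 1 rise and 8 falls of 20, also adjusted over the list alone, and under median-of-ratios scaling 4 higher and 3 lower, where the median of -0.23 became 0.22 (camera adjusted p = 0.429, upward). Ribosome biogenesis genes gave 6 falls of 8, or 7 adjusted over the list alone, 4 in all 4 scalings, with BRX1-1 down (-1.89) and the fibrillarin FIB2 down (-1.48) (camera adjusted p = 0.314). Root markers gave 2 falls of 9, also adjusted over the list alone, SCR (-1.95) and PYK10 (-2.14), and 1 higher and 2 lower under median-of-ratios scaling, with a median of 0.028, a mean of -0.21 and an upward sign in camera (adjusted p = 0.369). MAF2 was the flowering gene past the threshold (1 of 8, and 0 adjusted over the list alone), at -0.38 as deposited and 0.11 under median-of-ratios scaling, where the list gave 5 higher and 0 lower (camera adjusted p = 0.429, upward against a median of -0.17). With the chloroplast-encoded share as a covariate MAF2 was at -0.091 (adjusted p = 0.686). Reference genes gave 3 rises and 1 fall of 11, or 1 and 1 adjusted over the list alone, and 10 were higher and 0 lower under median-of-ratios scaling (camera adjusted p = 0.00822, and adjusted p = 0.539 with an estimated correlation).

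Across the 17628 genes the heat responses of the genotypes had a Pearson r of 0.938, a description across genes, which are not independent replicates. Of the genes called in wild type, 99.6% had the same sign in atdamt1. Both genotypes called 9863 genes in the same direction, 1363 higher and 8500 lower, against 171 and 5211 expected from independent lists, and 1 gene in opposite directions. Independence is a weak reference here, since both genotypes had the same treatment and a similar downward median shift. In wild type only 1062 genes were called, and in atdamt1 only 1866. In all 4 scalings, 1345 genes rose and 3378 fell in both genotypes. The deposited scale was among these scalings, so this count favours falls.

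**Figure D3:**
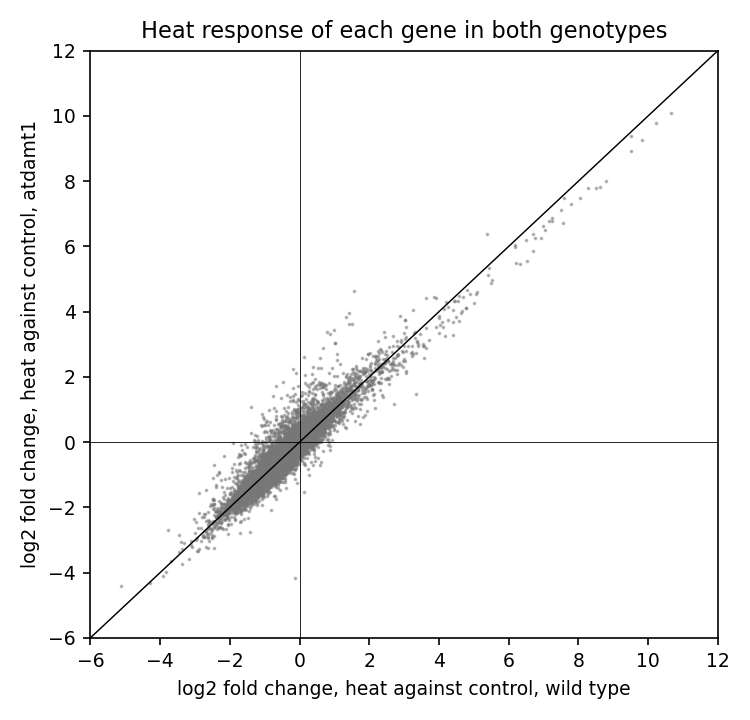
Log2 fold change of heat against control in wild type (x axis) and in atdamt1 (y axis) on the log2(RPKM + 1) scale, with 1 point per gene and the line of equal change. The 17628 genes follow the line with a Pearson r of 0.938.

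Without heat, 2 genes differed between atdamt1 and wild type, both higher in atdamt1. AT3G01345, annotated as an expressed protein on chromosome 3 at 129138 to 130749 of TAIR10.1, was at 109 ± 10.4 RPKM in atdamt1 and 0.16 ± 0.0707 RPKM in wild type (SD, n = 3), a log2 difference of 6.57 ± 0.77 (adjusted p = 0.0374, limma). AT1G75945, on chromosome 1 at 28515245 to 28515916 with 2 exon blocks, was at 26.3 ± 5.17 and 6.72 ± 1.98 RPKM, a log2 difference of 1.84 ± 0.23 (adjusted p = 0.0374, limma). At an unadjusted p below 0.05 there were 816 genes, and voom called 0. Both calls were lost with a pseudocount of 0.1, with no filter (adjusted p = 0.130 for both) and with the chloroplast-encoded share as a covariate (6.53 and 1.82, adjusted p = 0.0919 for both). AT3G01345 was also lost under median-of-ratios (adjusted p = 0.0642) and TMM scaling (adjusted p = 0.0629), and AT1G75945 in the fit of the control libraries alone (adjusted p = 0.516). In limma, 0 genes were called when any of the 6 control libraries or any of the 3 wild-type heat libraries was left out. Without atdamt1 heat replicate 1 the count was 1.

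No tested member of any fixed list passed limma over all genes in this comparison; adjusted over the list alone, 1 did, the clock gene LNK2 at 3.89 ± 0.805 RPKM in atdamt1 and 8.52 ± 1.76 in wild type (log2 -0.95 ± 0.22). Camera called 3 lists, relative to a median over all genes of -0.066. Photosynthesis genes were up (adjusted p = 0.00101, and adjusted p = 0.787 with an estimated correlation) with a median of 0.094 and a mean of -0.0041. Their mean difference was 0.078 under median-of-ratios, 0.082 under TMM and -0.099 under quantile scaling, so its sign depended on the scaling. RBCS2B, a small subunit gene of Rubisco, had 0.47 ± 0.14. Flowering-time genes were up (adjusted p = 0.0376, and adjusted p = 0.421 with an estimated correlation; median 0.069), and root markers were down (adjusted p = 0.0376, and adjusted p = 0.631 with an estimated correlation; median -0.71), with SHR, a root radial patterning gene, at -0.53 ± 0.19. The mean log2 level of the root markers was 3.15 ± 0.763 in wild type and 2.597 ± 0.154 in atdamt1 (SD, n = 3). The exact permutation p was 0.3, two-sided (adjusted p = 0.72). Wild-type control replicate 1 was the highest, while replicates 2 and 3 were at 2.919 and 2.53. The atdamt1 controls lay at 2.479 to 2.77, so the groups overlapped and the difference leaned on that 1 library. The list was not tested without it. With the chloroplast-encoded share as a covariate the root marker call missed the threshold (adjusted p = 0.0718) at a median of -0.60, of about the same size.

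After heat, 0 genes differed between the genotypes at adjusted p below 0.05 in limma, with 1326 at an unadjusted p below 0.05 and 0 with voom. Array weights called 7 genes and a pseudocount of 0.1 called 2. A count of 1 came with median-of-ratios scaling, TMM scaling or the replicate block, and without wild-type control replicate 1 or without atdamt1 heat replicate 1. The median half-width of the 95% interval was 0.31 (log2). The chloroplast-encoded share, at 3.17% to 6.01% in atdamt1 and 0.39% to 4.05% in wild type after heat, differed along with this comparison. The heat shock protein gene HSP22 was at 239 RPKM in atdamt1 and 394 RPKM in wild type (log2 -0.75 ± 0.33), and the heat shock transcription factor gene HSFA7B was at 52.4 and 84.7 RPKM (log2 -0.77 ± 0.45). LNK2 had -0.59 ± 0.22, the superoxide dismutase MSD1 -0.27 ± 0.08, the cell-wall enzyme XTH22 -0.37 ± 0.11 and CBP60G 0.84 ± 0.32, none past the threshold. SEP3 alone passed adjusted over the list alone, in a list with 1 tested member (log2 -1.07 ± 0.46).

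Camera called 10 lists in this comparison, relative to a median over all genes of -0.083. Small heat shock proteins (adjusted p = 0.00343, and adjusted p = 0.787 with an estimated correlation) and other chaperones (adjusted p = 7.33e-05, and adjusted p = 0.787 with an estimated correlation) were down, with medians of -0.54 and -0.43. Both calls ended without wild-type heat replicate 1 (adjusted p = 0.645 and 0.514) and without atdamt1 heat replicate 3 (adjusted p = 0.858 and 0.270). With the chloroplast-encoded share as a covariate, chosen after seeing the data, camera called 5 lists, and 0 with an estimated correlation. The chaperones were called at a smaller median (adjusted p = 0.0294, -0.43 to -0.18, and adjusted p = 0.896 with an estimated correlation). Medians moved further from 0 for cell cycle (8.12e-07, -0.31 to -0.39), abscisic acid (0.000801, 0.038 to 0.21) and clock genes (0.00208, 0.076 to 0.17). Salicylic acid genes were called higher with the covariate (0.0132, -0.058 to 0.19). Calls ended with smaller medians for small heat shock proteins (0.420, -0.54 to -0.15), ER folding (0.290, -0.19 to -0.11), reactive oxygen (0.0630, -0.27 to -0.093), photosynthesis (0.862, 0.041 to -0.011) and reference genes (0.420, -0.20 to -0.096). The flowering call missed the threshold (0.0630) at a median that went from 0.069 to 0.091. Over the 6 heat libraries left out in turn, the adjusted p of the small heat shock proteins and of the chaperones ran from 3.34e-08 to 0.858 and from 4.9e-14 to 0.514. ER folding (adjusted p = 0.0376, and adjusted p = 0.787 with an estimated correlation), reactive oxygen (adjusted p = 0.00591, and adjusted p = 0.539 with an estimated correlation), cell cycle (adjusted p = 0.00348, and adjusted p = 0.787 with an estimated correlation) and reference genes (adjusted p = 0.00792, and adjusted p = 0.539 with an estimated correlation) were also down. Photosynthesis (adjusted p = 0.000922, and adjusted p = 0.787 with an estimated correlation), abscisic acid (adjusted p = 0.0291, and adjusted p = 0.826 with an estimated correlation), clock (adjusted p = 0.00268, and adjusted p = 0.601 with an estimated correlation) and flowering genes (adjusted p = 0.0122, and adjusted p = 0.421 with an estimated correlation) were up, with medians of 0.041, 0.038, 0.076 and 0.069. The mean difference of the photosynthesis genes was 0.14 under median-of-ratios, 0.13 under TMM and -0.061 under quantile scaling. The mean log2 level of the small heat shock proteins was 9.03 ± 0.56 in wild type and 8.50 ± 0.69 in atdamt1 (SD, n = 3; exact permutation p = 0.4, two-sided), and the smallest exact p for 3 against 3 is 0.1. The list means of the reactive oxygen, cell cycle and reference genes were lower in each of the 3 atdamt1 heat libraries than in any wild-type heat library, by log2 differences of -0.23, -0.27 and -0.18 at that smallest p of 0.1. Adjusted over 36 such comparisons, 18 lists in 2 treatments, the p was 0.72 for these 3 lists and for the small heat shock proteins. All 3 kept this direction in all 4 scalings, but under median-of-ratios, TMM and quantile scaling the differences were smaller, at -0.13, -0.13 and -0.12 for reactive oxygen, -0.19, -0.19 and -0.18 for cell cycle and -0.078, -0.085 and -0.068 for reference genes. The exact permutation p of the reference genes was 0.3 under median-of-ratios and TMM. Clock genes (0.17, 0.16 and 0.15) and flowering genes (0.18, 0.17 and 0.16) were higher in atdamt1 under these 3 scalings at the exact permutation p of 0.1 (adjusted p of 0.72, 0.72 and 0.6), against 0.066 (p = 0.4) and 0.088 (p = 0.2) as deposited. Flowering genes had the same exact permutation p in control under these 3 scalings (0.13, 0.14 and 0.16), so their difference was not particular to heat.

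**Figure D4:**
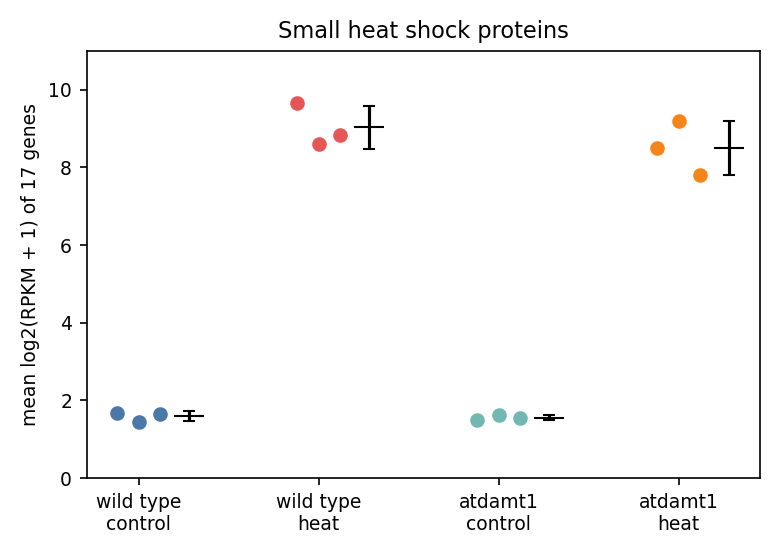
Mean log2(RPKM + 1) of 17 small heat shock proteins in each library, with 3 libraries per group as points and the mean ± SD in black. The wild-type heat libraries lie at 8.60 to 9.66 and the atdamt1 heat libraries at 7.80 to 9.18, so the groups overlap.

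The test of the difference between the heat responses called 0 genes in limma, with 596 at an unadjusted p below 0.05 and 0 with voom. HSP18.5 rose 8.28-fold in wild type and 5.83-fold in atdamt1 (interaction -0.54 ± 0.30), and the superoxide dismutase FSD1 had -0.56 ± 0.18, XTH22 -0.58 ± 0.16, CBP60G 1.01 ± 0.46 and the clock gene LHY 0.52 ± 0.27, each with an adjusted p of 0.979 in limma. Adjusted over the list alone, 0 members passed in any list. Leaving out atdamt1 heat replicate 1 gave 1 gene.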

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

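The tests that leave out single libraries from the heat shock lists, the exact test of the list means and the chloroplast-encoded share as a covariate of the lists were chosen only after the result was seen. By the interaction test in camera at a preset correlation, the heat response of 6 gene lists differed between the genotypes, and 0 did with an estimated correlation. That setting called no fixed list in any comparison, not even small heat shock proteins with heat in wild type, where 16 of 17 rose. A missing call with it therefore does not argue against a list difference. Small heat shock proteins had lower heat responses in atdamt1 (adjusted p = 0.00348, median -0.54, and adjusted p = 0.787 with an estimated correlation), as did other chaperones outside the ER (adjusted p = 0.000948, median -0.37, and adjusted p = 0.787 with an estimated correlation). Reactive oxygen genes were lower in this contrast (adjusted p = 0.00076, median -0.26, and adjusted p = 0.421 with an estimated correlation). Auxin genes (adjusted p = 0.0376, median 0.21, and adjusted p = 0.860 with an estimated correlation), clock genes (adjusted p = 0.00292, median 0.26, and adjusted p = 0.601 with an estimated correlation) and root markers (adjusted p = 0.00739, median 0.47, and adjusted p = 0.539 with an estimated correlation) were higher. The root marker means differed between genotypes by -0.554 in control and 0.0973 in heat. Their interaction therefore came more from the controls, where wild-type replicate 1 stood above the other libraries. Without wild-type heat replicate 1 the interaction adjusted p was 0.359 for the small heat shock proteins and 0.523 for the chaperones, and without atdamt1 heat replicate 3 it was 0.456 and 0.329. With the chloroplast-encoded share as a covariate it was 0.309 and 0.0704, with medians of -0.068 and -0.11, and root markers lost their call and reversed (0.851, median -0.028). The auxin call missed the threshold (0.420) at a median of 0.22 that had not shrunk, so that loss does not tie it to the share. Reactive oxygen genes stayed past the threshold at a smaller median (0.00895, -0.10) and clock genes at a median of 0.29 (0.00156). Cell cycle (0.0023, -0.14 to -0.19) and photosynthesis genes (0.0208, -0.037 to -0.093) were then called lower, and abscisic acid (0.0284, 0.068 to 0.41) and salicylic acid genes (0.0158, 0.074 to 0.30) higher, with 0 lists called with an estimated correlation. Of 100 splits of the libraries that exchanged genotype within treatments, 71 called at least 6 lists, with up to 11 in another split, so chance is not excluded.

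At the preset correlation, camera called the small heat shock protein and chaperone lists lower in atdamt1 than in wild type after heat, with 0 of 17 and 0 of 29 members past the threshold in limma and adjusted p = 0.787 for both with an estimated correlation. A candidate explanation is 1 library, wild-type heat replicate 1: without it the adjusted p was 0.645 for the small heat shock proteins and 0.514 for the chaperones, but without atdamt1 heat replicate 3 the values were 0.858 and 0.270, and with each of the other 4 heat libraries left out in turn both lists stayed past the threshold. Another is a difference among the heat libraries that goes with their chloroplast-encoded share: wild-type replicates 1 and 3 and atdamt1 replicate 2, with 0.628%, 0.39% and 3.17%, had means of 9.66, 8.82 and 9.18 for the small heat shock proteins and 7.80, 7.06 and 7.40 for the chaperones, above wild-type replicate 2 and atdamt1 replicates 1 and 3, with 4.05%, 6.01% and 5.58% (8.60, 8.51 and 7.80, and 6.87, 6.67 and 6.32). With that share as a covariate the median difference of the small heat shock proteins went from -0.54 to -0.15 (interquartile range over members 0.37 and 0.20) and the call ended with it (adjusted p = 0.420), while the chaperones went from -0.43 to -0.18 (0.19 and 0.0828) and stayed past the threshold (adjusted p = 0.0294, and adjusted p = 0.896 with an estimated correlation). A genotype difference in heat, with an exact permutation p of 0.4 for the mean of either list where the smallest possible is 0.1, cannot be told apart from these with 3 libraries per group and a share that differs along with genotype.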

How the results depend on the processing

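Voom, the chloroplast-encoded share as a covariate (of genes and of lists) and the fits of lists without wild-type heat replicate 1 were tests chosen only after the result was seen. Total heat counts stayed within 1.5 times the reported ones except with a 2-fold threshold (3589 in wild type and 3827 in atdamt1) and, in atdamt1, with the covariate (6489). The split of these totals into higher and lower genes moved further under the other scalings. Leaving out libraries gave 9859 to 11057 genes in wild type, 10473 to 11717 in atdamt1 and an r of 0.907 to 0.954. The genotype count in control was 0 with a pseudocount of 0.1, no filter, voom, the covariate and adjusted p below 0.01, was 1 with median-of-ratios, TMM and the single contrast, and ranged from 0 to 2 over left-out libraries. In heat it was 2 with a pseudocount of 0.1, 1 with median-of-ratios, TMM and the replicate block, 7 with array weights, and 0 to 1 over left-out libraries; the interaction gave 0 to 1. The labels do not say that a replicate number marks a shared batch. Over all groups, same-number correlations ran from -0.425 to 0.527 with a median of 0.0549, and 4 of 12 libraries correlated best with their own number. In controls the chloroplast-encoded share fell with the number, at 1.07%, 0.613% and 0.394% in wild type and 0.979%, 0.497% and 0.32% in atdamt1. Same-number controls of the genotypes correlated at 0.211, 0.035 and 0.527. The heat shares had no such order, and a batch shared by number among controls is not excluded. With the replicate block the counts were 10952, 11749, 2, 1 and 0. The alternatives for a count table were not run, since the table holds RPKM.

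AT1G19340 passed between genotypes in control with a pseudocount of 5 (-0.39) and array weights (-1.02), and in heat with array weights (-0.86). Its fall with heat was no longer past the threshold in wild type with median-of-ratios (-0.35), TMM (-0.35) and quantile scaling (-0.18), and in atdamt1 with quantile scaling (-0.32) and the covariate (-0.45). Its interaction of 0.12 turned to -0.39 with a pseudocount of 0.1, -0.032 with median-of-ratios, -0.039 with TMM, -0.14 with quantile scaling and -0.59 with voom. Over left-out libraries the values were -1.06 to -0.89 (genotype in control), -0.91 to -0.73 (genotype in heat), -0.77 to -0.65 (heat in wild type), -0.65 to -0.47 (heat in atdamt1) and 0.044 to 0.23 (interaction). Values of this gene were low against the added 1, and with the smaller pseudocount and voom its relative fall was larger in atdamt1. The ratio of its means to wild type likewise went from 0.349 in control to 0.246 in heat. None of these interactions passed the threshold. For the other changes the cause was not tested.

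Under median-of-ratios, TMM and quantile scaling in wild type, FLM reversed to 0.20, 0.20 and 0.22, MAF3 to 0.15, 0.16 and 0.11 and MAF2 to 0.17, 0.17 and 0.12; MAF2 in atdamt1 reversed to 0.11, 0.11 and 0.057. SEP3 reversed to -0.013 in the control genotype contrast without atdamt1 control replicate 2, where left-out libraries gave up to 0.40, and to 0.42 for heat in atdamt1 with the covariate, and the LOX3 interaction to 0.00337 with the covariate. With an estimated correlation 0 lists were called in each comparison; median-of-ratios called 5 for genotype in control, and without wild-type heat replicate 1 the counts were 12, 12, 4, 8 and 4. With the covariate, 5 lists were called for genotype in heat. List directions reversed at these adjusted p-values, of which photosynthesis in the interaction with the covariate (0.0208, downward) was past the threshold. With the replicate block they were other regulators in control (0.972) and heat shock factors in the interaction (0.938). With median-of-ratios they were root markers for heat in atdamt1 (0.932) and, for genotype in control, small heat shock proteins (0.924), chaperones (0.771), other regulators (0.776) and abscisic acid (0.978). Without wild-type heat replicate 1 they were other regulators in control (0.987), in heat (0.679) and in the interaction (0.752), heat shock factors in heat (0.333), methylation genes in heat (0.557) and photosynthesis in the interaction (0.523). With the covariate they were also cell cycle (0.895) and root markers (0.610) for heat in atdamt1, other regulators in control (0.921), in heat (0.894) and in the interaction (0.894), and jasmonic acid (0.614) and root markers (0.851) in the interaction. For genotype in heat with the covariate they were heat shock factors (0.565), photosynthesis (0.862), auxin (0.868), methylation genes (0.852) and root markers (0.0831).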

Other observations

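The gene families, the genotype average, the distance to AT1G19340 and the question of line variation were tests chosen only after the result was seen. The 5 tested trans-acting siRNA precursors all fell with heat in both genotypes and in all 4 scalings, with median log2 changes of -3.83 in wild type and -3.98 in atdamt1 (camera adjusted p = 0.0953 with an estimated correlation). Among genes chosen after their values were seen, TASIR-ARF fell from 6.30 to 0.0926 RPKM in wild type. Of 19 glucosinolate biosynthesis genes, 13 fell and 1 rose in each genotype, with 8 falls in all 4 scalings and 2 higher and 8 lower under median-of-ratios scaling, and the regulator MYB34 fell (-3.12 and -3.15) (camera adjusted p = 0.898 and 0.930 with an estimated correlation). Core histone genes fell in 25 of 30 cases in each genotype, with 15 and 19 in all 4 scalings; under median-of-ratios scaling 3 were higher and 17 lower in wild type (camera adjusted p = 0.805 with an estimated correlation). Cytosolic ribosomal protein genes fell in 96 of 194 cases in wild type and 152 in atdamt1, of which 19 and 43 held in all 4 scalings, and under median-of-ratios scaling the wild-type direction was mixed, with 26 higher and 21 lower (camera adjusted p = 0.935 and 0.898 with an estimated correlation).

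Mitochondrial-encoded genes rose in 49 of 50 cases in wild type and 48 in atdamt1, in all 4 scalings, with median changes of 1.62 and 1.72, and this call held with an estimated correlation (camera adjusted p = 0.0215). Together they held 0.0126% to 0.0344% of the RPKM sum in controls and 0.109% to 0.155% after heat. Members could pass the expression filter through the heat libraries alone, and genes moving with 1 share are not separate cases. The libraries hold poly(A) RNA, so the changes are those of captured organelle RNA. Chloroplast-encoded genes gave 3 rises and 8 falls of 68 in wild type as deposited, with a median of 0.21, but 5 higher and 2 lower under median-of-ratios scaling, and 3 rises and 2 falls held in all 4 scalings (camera adjusted p = 0.805 with an estimated correlation). In atdamt1 they gave 46 rises and 3 falls, with a median of 1.43, and 46 and 2 held in all 4 scalings (camera adjusted p = 0.353 with an estimated correlation). Their genotype difference in heat had a median of 1.14, with 0 genes past the threshold in limma and a camera adjusted p of 0.0559 with an estimated correlation. The asparagine synthetase gene ASN1, also chosen after its values were seen, rose by 5.37 in wild type and 6.39 in atdamt1 (interaction 1.02 ± 0.29, adjusted p = 0.979, limma).

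More genes fell than rose with heat on the deposited scale. A candidate explanation is a small set of genes taking a larger share of the reads after heat. The 100 genes with the largest gain held 9.46% of reads in wild-type control and 21.7% after heat. Leaving them out of the totals moved the median log2 change from -0.41 to -0.25. The range was -0.27 to -0.22 when single libraries were left out with the same 100 genes. These genes were chosen by their gain in the same libraries, so the direction of that move was fixed in advance. Only its size carries information, and the median stayed below 0 without these genes. Organelle-encoded genes have no length and were not among them. A fall in the amount of mRNA of most genes per seedling cannot be told apart from this, since the median of -0.41 is a share of each library total.

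Averaged over both treatments, 5 genes differed between genotypes in limma: AT1G75945, AT3G05955, AT3G01345 and AT5G26270 were higher in atdamt1 and AT1G19340 was lower (-0.90 ± 0.10, adjusted p = 0.0081). Of 100 splits that exchanged genotype within treatments, 2 gave at least 5 genes, the real one and 1 with 1191, and without the mutated gene AT1G19340 the real count was 4 and 3 of 100 splits gave at least as many, but the contrast was chosen after 2 of the genes had been called in control, so these splits alone do not exclude chance. For the 4 genes higher in atdamt1 on the average of both treatments, sequence linked to AT1G19340 and carried along with the mutant allele would place most of them nearby, and 0 of the 4 lie within 5 Mb of it. Reads shared with near-identical copies are argued against by a median of 0 percent of 50-base exon words found elsewhere, although AT3G05955 had 14.5 percent. Variation of the mutant line unrelated to AT1G19340 may account for them and was not decided, since the labels name 1 mutant; 5 of 6 atdamt1 libraries lay above all wild-type libraries of their treatment in AT3G01345.

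Splits of 3 libraries against 3 number 10 and cannot give a share under 0.05. For genes changed by heat in wild type the real split gave 10926 and the highest other 0 (1 of 10 splits as large), and for atdamt1 11730 and 0 (1 of 10). For the genotype difference in control the real split gave 2 genes and the highest other 29 (2 of 10), a split that calls several times the real count and points to a structure of the samples, and in heat 0 and 3 (10 of 10). For lists the real counts and the highest others were 12 and 14 for heat in wild type (4 of 10), 12 and 14 for heat in atdamt1 (2 of 10), 3 and 8 for genotype in control (9 of 10), and 10 and 9 for genotype in heat (1 of 10). For the interaction, 100 of 100 splits gave at least the real count of 0 genes, and the highest gave 1814. The splits with 1814 and 1191 genes both set the heat libraries with chloroplast-encoded shares of 4.05%, 6.01% and 5.58% against those with 0.628%, 0.39% and 3.17%. In the heat comparison that grouping alone gave 3 genes, and both splits also regrouped the controls. In the split with 1814 genes the share ran in opposite directions in controls and heat. Within each treatment its groups were those higher and lower on the second principal component. The counts point to a structure of the samples, which the share alone does not describe.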
